A study of Mus musculus with 16 samples.

How the data were processed

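Per the sample labels, 1 ng of RNA from 150000 to 800000 sorted YFP+ CD4+ T cells was amplified with the NuGEN Ovation V2 kit and sequenced as single 50-nt reads on an Illumina HiSeq, with 4 libraries per lane. The cells came from C57BL/6 mice with Cre-mediated deletion of Dgcr8 in T cells and without Tbx21. There were 4 groups (control mimic, miR-23a, miR-24 and miR-27a) of 4 libraries, and groups and replicate numbers were taken from the sample titles. The labels do not give the mouse, lane or date of each library.

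The authors deposited 1 file per library with raw read counts for 23337 gene symbols and 5 summary lines, which were left out of library sizes and tests. The submitters' processing notes name Bowtie2, TopHat, DESeq and the mm10 build without versions. The counter, the annotation and the strand setting are not stated. The values are whole numbers whose totals differ between libraries. Gene reads per library, in replicate order, were 11995286, 4086654, 11370150 and 12582408 for miR-23a, 5863004, 11427485, 13220646 and 10216730 for miR-24, 2972976, 2120408, 13714841 and 6289783 for miR-27a, and 51474, 10659627, 11367506 and 7272860 for control. The summary lines held 64.6% to 77.6% of all lines' reads, mostly reads without a gene (28.6% to 44.0%) or without a unique place (27.9% to 44.8%).

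Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group (12952) were scaled by TMM and fitted in all 16 libraries with group as the only term, and each comparison was tested with the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes, and log2-CPM a prior count of 2. The biological coefficient of variation was 0.389. A total of 40 gene lists with 904 members, written from general knowledge before the data were examined along with the comparisons, the tests and the alternatives other than those named below as added, was tested with camera of limma 3.58.1 on voom values (preset inter-gene correlation 0.01, adjusted over the lists of each comparison). Camera was repeated with an estimated correlation.

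The replicate number was tested as a pairing of libraries. Group means were removed and same-numbered libraries correlated over genes with a mean log2-CPM above 5; a pair of groups counted as paired when all 4 correlations passed 0.1. Control and miR-27a met this (0.198 to 0.611, with the same number as the best match for 4 of 4 libraries), although over all genes tested 3 of 4 passed (lowest 0.0607). So did miR-23a with miR-24 (lowest 0.350) and with miR-27a (lowest 0.257). Control against miR-23a (lowest -0.12), control against miR-24 (lowest 0.0304) and miR-24 against miR-27a (lowest -0.0072) did not, each with 3 of 4 over 0.1. Among the comparisons whose called genes are given below, a fit with the replicate number as a block stands by this rule beside the result only for miR-27a against control. For miR-23a against miR-24 and against miR-27a, no called genes are given. These comparisons enter tests of seed sites, of seed matches and of a gene list, which are given without the block. Over all 4 groups together, however, only the real one of 13824 assignments of numbers had so high a mean same-number correlation. The results of the other comparisons therefore leave out a likely pairing. For miR-23a and miR-24 against control and miR-24 against miR-27a, the block called 55, 591 and 572 genes, against 17, 110 and 114 without it.

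Named genes follow a rule. For each comparison with control they are (a) up to 6 genes with the highest and 6 with the lowest log2 fold change among those with adjusted p under 0.05, mean log2-CPM of at least 3 and no overlap between the libraries of both groups, leaving out predicted genes and small RNA genes; (b) Il4, Il5, Il13, Il10, Gata3, Il4ra, Stat6, Maf, Ikzf1 and Nfatc2; (c) up to 3 members of each list with several called members; and (d) the 5 genes with an 8mer site of the mimic that fell with the smallest adjusted p. For miR-24 against miR-27a they are (a) and (b), for overlaps up to 5 genes per direction, and Dgcr8 and Tbx21 are given throughout. Other genes are said to be named after their values were seen.

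Seed sites were searched in the longest annotated 3-prime UTR of each gene in GENCODE M21 (GRCm38, the assembly of mm10). Of the symbols, 20953 matched directly, 1888 through an older symbol and 464 not at all, 32 were dropped as repeated matches, and 12005 tested genes were searched. The labels give neither the arm nor the sequence of the mimics, so the 3p arms were assumed from general knowledge: miR-23a AUCACAUUGCCAGGGAUUUCC (8mer site AATGTGAA), miR-24 UGGCUCAGUUCAGCAGGAACAG (CTGAGCCA) and miR-27a UUCACAGUGGCUAAGUUCCGC (ACTGTGAA), with 7mer-m8 and 7mer-A1 sites as their first and last 7 bases. Genes with and without a site were compared with camera and sites among called genes with Fisher's exact test, two-sided. All 7-mers present in at least 100 genes (15735 of 16384) were ranked by a regression of the log2 fold change with 3-prime UTR length, GC content and expression as covariates, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.

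The alternatives were RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 4 libraries, the replicate block, the libraries of both groups alone, DESeq2 1.42.0 (adjusted p not given by its filter for 2766, 761, 510 and 1513 genes of miR-23a, miR-24 and miR-27a against control and miR-24 against miR-27a), limma-voom with sample weights, leaving out each library, 8mer sites only, sites in any annotated 3-prime UTR and a background matched on 3-prime UTR length and expression. A block without control replicate 1 and library sizes without Rn45s were added after the data were seen. The pipeline was tested on simulated data with the observed depths, in 12711 genes, with the changed genes drawn from those with a mean log2-CPM of at least 3. Folds of 2, 4 and 8 were recovered in 19.4%, 88.1% and 98.5% of changed genes for miR-23a, 22.4%, 86.6% and 97.0% for miR-24 and 17.9%, 88.1% and 93.9% for miR-27a, with 5.52%, 5.52% and 6.34% false calls. In a further simulation, a list of 35 members shifted by 0.5 (log2) was called along with 1 other list, and a 7-mer with a planted shift of 0.3 was ranked 1.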

Results

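Messenger RNA was measured by sequencing in mouse CD4+ T cells that lack Dgcr8, a protein needed to make most microRNAs, and Tbx21, the transcription factor T-bet that drives Th1 cells. The cells were stimulated through CD3 and CD28 with 10 U/ml of IL-4 for 3 days, rested in 20 U/ml of IL-2 for 2 days, and transfected on day 1 and day 4 with 500 nM of a synthetic double-stranded microRNA, called a mimic. The mimics were miR-23a, miR-24, miR-27a and a control mimic whose sequence the labels do not give. Each of the 4 groups had 4 libraries, 16 in all, and the series text describes them as at least biologic triplicates without saying which libraries came from separate mice. The p-values therefore measure the spread between libraries.

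Reads counted in genes ranged from 2120408 in miR-27a replicate 2 to 13714841 in miR-27a replicate 3 in 15 libraries. Control replicate 1 held 51474, so that 1 read there was worth 16.3 CPM (counts scaled to a common library size) and 3 reads 48.8 CPM. In it 7292 genes had a read, against 13400 to 15847 in the others. Rn45s, the 45S ribosomal RNA precursor, took 0.30% to 19.1% of gene reads. Its share averaged 2.10% ± 1.73% (SD, n = 4) in the control group, 6.06% ± 4.74% with miR-23a, 9.07% ± 7.54% with miR-24 and 6.16% ± 3.89% with miR-27a. Genes with a read averaged 12620 ± 3561 in the control group, which includes control replicate 1, 15083 ± 593 with miR-23a, 15246 ± 567 with miR-24 and 14235 ± 620 with miR-27a. Over these measures, the gene reads and the reads without a gene or a unique place, the exact permutation p of a mimic against control was 0.0571 or more (two-sided, unadjusted). With 4 against 4 libraries it cannot fall below 0.0286, so a difference between the groups is not excluded.

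Dgcr8 transcripts were present at 32.5 to 58.4 CPM in 15 libraries and at 114 CPM, from 7 reads, in control replicate 1. Gene counts cannot tell a transcript that lacks the deleted exon from an intact one, so this value does not check the genotype. Tbx21 had 0 to 58 reads per library, at most 5.20 CPM, and the annotation of the mutant allele is not in the labels. The libraries held few transcripts of other cell types. The 8 class II antigen presentation genes summed to 65.2 ± 31.8 CPM (SD, n = 4) in the control group, 102 ± 54.0 with miR-23a, 69.2 ± 31.5 with miR-24 and 125 ± 74.8 with miR-27a. Cd74, the invariant chain, stood at 14.6 ± 6.57 CPM in the control group and 42.2 ± 34.9 CPM with miR-27a. Dendritic cell markers summed to 45.2 ± 11.2 CPM in the control group and 80.1 ± 17.0 CPM with miR-24, and myeloid markers to 23.6 ± 6.83 and 38.7 ± 6.75 CPM. The dendritic sums did not overlap between miR-24 (64.3 to 104 CPM) and control (32.6 to 59.0 CPM), while those of miR-23a and miR-27a overlapped the control. None of the 8 marker lists passed limma's camera test in a comparison of a mimic with control (smallest adjusted p = 0.114, class II genes with miR-27a). Most of these lists had only 1 to 5 tested genes, from 1 for granulocyte to 5 for myeloid markers, so camera could hardly call them.

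The comparison of miR-23a with the control mimic asked which transcripts respond to the member of the miR-23, miR-24 and miR-27 cluster that the series title leaves out. The 17 genes that changed all fell. Sh3bgrl, a small thioredoxin-like protein, fell from 133 ± 46.9 CPM to 30.1 ± 7.18 CPM (SD, n = 4 each), a log2 fold change of -2.20 ± 0.34 (SE). Sft2d1, a vesicle transport protein, changed by -2.15 ± 0.30, Atp5f1, a subunit of mitochondrial ATP synthase, by -1.94 ± 0.28, and Auh, an enzyme of leucine breakdown that also binds RNA, by -1.73 ± 0.25. The zinc finger protein gene Zfp395 (-1.40 ± 0.22) and Cggbp1, which encodes a protein that binds CGG repeats (-1.36 ± 0.19), fell in all 4 libraries as well. Rps29, a protein of the small ribosomal subunit, fell from 102 ± 19.5 to 26.0 ± 10.4 CPM, and Hmgn2, a nucleosome-binding protein, changed by -1.64 ± 0.32. Both genes have near-identical copies elsewhere in the genome, so their counts are less certain.

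In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 8 genes ranged from 0.00582 to 0.0457. The test called 0 genes higher and 17 lower of 12952 tested, with 1456 genes at an unadjusted p under 0.05, while DESeq2 called 6 higher and 38 lower and limma with sample weights 0 higher and 17 lower. No overlap between the 4 miR-23a and the 4 control libraries was seen for 673 genes, where chance gives 2.86% of genes. Atp5f1, Auh, Cggbp1, Rps29, Sft2d1 and Sh3bgrl kept an adjusted p under 0.05 in edgeR in each of the 8 fits that left out 1 library. Hmgn2 lost it in 6 of them, those without control replicate 1, 2 or 3 or miR-23a replicate 2, 3 or 4 (largest 0.198), and Zfp395 without control replicate 3 (0.0543). The count was 8 without control replicate 3 and 10, 9 and 10 without miR-23a replicate 2, 3 and 4. A fit of these 8 libraries alone called 2 genes.

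Among the 40 gene lists fixed before the data were examined, miR-23 targets reported elsewhere were lower with miR-23a and p53 target genes higher, in calls that did not hold with an estimated correlation. Camera gave the miR-23 targets an adjusted p of 0.000706 and the p53 targets 0.00749. The adjusted p with an estimated correlation was 0.0899 and 0.999. Of the 17 measured miR-23 targets, 15 had a negative fold change, 1 was called over all genes (Hmgn2) and 4 when adjusted over the list alone (Hmgn2, Xiap, Ppif and Tab3, of which the last 3 were named after their values were seen). Xiap, an inhibitor of caspases, stood at -1.01 ± 0.31. Of the 20 p53 targets, 18 had a positive fold change, 0 were called over all genes and 1 adjusted over the list alone (Aen, a nuclease of the p53 response, 1.39 ± 0.37, named after its value was seen). Without control replicate 2 or miR-23a replicate 4, 1 of both lists was called, and without control replicate 4 the count was 4.

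Transcripts of the Th2 programme, the IL-4 driven state that these culture conditions favour, did not pass the test with miR-23a. Among the 38 measured Th2 genes, 18 fold changes were positive and 20 negative, and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 0.781). Il4, the cytokine that drives Th2 cells, stood at -0.76 ± 0.42, Gata3, the transcription factor that defines them, at -0.11 ± 0.40, Il13 at 0.13 ± 1.13 and Il5 at 1.10 ± 0.67. Maf, an activator of Il4 transcription, stood at -1.31 ± 0.47 (edgeR adjusted p = 0.350), and Il10, Il4ra, Stat6, Ikzf1 and Nfatc2 had adjusted p from 0.430 to 0.947.

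The comparison of miR-24 with control addressed the effect of a microRNA that the series title links to Th2 cytokine production. With miR-24, 38 genes rose and 72 fell. Pcx, the mitochondrial enzyme pyruvate carboxylase, rose from 2.20 ± 1.78 to 29.7 ± 13.1 CPM (SD, n = 4 each; log2 fold change 3.33 ± 0.53), and Hbegf, a growth factor that binds the EGF receptor, by 2.87 ± 0.47. The amino acid transporter gene Slc7a5 rose by 2.54 ± 0.49, the cell cycle inhibitor gene Cdkn2b by 2.23 ± 0.52, the adhesion molecule gene Amica1 by 2.18 ± 0.50 and the drug efflux pump gene Abcb1b by 2.12 ± 0.38. Tcf7, a transcription factor of naive and memory T cells that also promotes Gata3 expression, fell from 599 ± 263 to 108 ± 42.2 CPM (-2.48 ± 0.44), and Epas1, a hypoxia-inducible transcription factor, from 1471 ± 602 to 273 ± 128 CPM (-2.45 ± 0.43). Control replicate 1 had 0 reads of Pcx, Hbegf, Cdkn2b, Amica1 and Abcb1b, and since 1 read there is 16.3 CPM, it says little about these genes.

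Also lower with miR-24 were Myo6, an actin motor (-2.65 ± 0.48), P2rx7, an ATP-gated ion channel (-2.19 ± 0.49), Chst2, a sulfotransferase (-2.13 ± 0.37), Slc25a23, a mitochondrial carrier (-2.02 ± 0.34), and G6pdx, the enzyme that opens the pentose phosphate pathway (-1.69 ± 0.32). Sub1, a transcriptional coactivator (-1.42 ± 0.24), Frmd8 (-1.35 ± 0.23) and Avl9 (-1.21 ± 0.21) had the smallest adjusted p among genes with an 8mer site of miR-24, together with G6pdx and Tada2b, an adaptor of a histone acetyltransferase complex (-1.57 ± 0.28). The libraries of both groups overlapped for Tada2b, since control replicate 1 had 0 reads of it. Of the calcium and NFAT signalling list, Clcn3, a chloride transporter (-1.18 ± 0.24), and Nfatc3, a transcription factor activated by calcium (-0.93 ± 0.19), fell, and Klf2, a factor of T cell quiescence and trafficking, changed by -1.32 ± 0.29.

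The edgeR test gave these 20 genes adjusted p from 0.00946 to 0.0477, among 1842 genes at an unadjusted p under 0.05 and 878 genes without overlap between the groups (chance gives 2.86%). Avl9, Chst2, Epas1, Frmd8, Hbegf, Myo6, Pcx, Slc25a23, Sub1 and Tcf7 stayed under 0.05 in all 8 fits without 1 library. Without control replicate 3, edgeR called 35 genes and lost Abcb1b, Amica1, Cdkn2b, Clcn3, G6pdx, Klf2, Nfatc3, P2rx7 and Slc7a5, and without miR-24 replicate 2 it called 39 and lost the same genes except Abcb1b, and Tada2b. Without miR-24 replicate 3 it called 55 and lost Amica1, Cdkn2b, Clcn3, Klf2, Nfatc3 and P2rx7, and without miR-24 replicate 4 it called 66 and lost Cdkn2b, Klf2, Nfatc3 and P2rx7. Amica1 was also lost without control replicate 1, 2 or 4 or miR-24 replicate 1, Cdkn2b without control replicate 1, 2 or 4, Klf2 and Nfatc3 without control replicate 2 or 4, Clcn3 without control replicate 2, Slc7a5 without control replicate 4, and P2rx7 without control replicate 1 or miR-24 replicate 1 (largest adjusted p 0.223, P2rx7). A fit of the libraries of both groups alone called 34 genes, and DESeq2 called 225, 110 higher and 115 lower.

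The Th2 list as a whole was lower with miR-24, with 29 of 38 fold changes negative (camera adjusted p = 5.98e-05), in a call that did not hold with an estimated correlation (camera adjusted p = 0.508). Called over all genes were Epas1 and Tcf7, and adjusted over the list alone also Maf (-1.48 ± 0.47), Ikzf1 (-0.61 ± 0.17) and Irf4 (-0.68 ± 0.21), a transcription factor needed for Th2 cytokines that was named after its value was seen. The cytokine genes were spread around the control: Il4 at -0.79 ± 0.42, Il5 at 0.38 ± 0.67, Il13 at 1.17 ± 1.14 and Il10 at -1.21 ± 0.86, and Gata3 stood at -0.74 ± 0.40 (edgeR adjusted p from 0.412 to 0.838 for these 5 genes). Il4ra (0.16 ± 0.36), Stat6 (-0.06 ± 0.25) and Nfatc2 (0.11 ± 0.26) did not pass the test. Il4 carries an 8mer site of miR-24, CTGAGCCA, in its annotated 3-prime UTR at chromosome 11, 53612554 to 53612561 (GRCm38, minus strand). Its fold change was similar with miR-23a (-0.76) and miR-27a (-0.74), of which it holds no site, so the value is not particular to miR-24.

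Other lists moved with miR-24 too. Ribosomal protein genes of the cytosol were higher, 36 of 40 with a positive fold change and a median of 0.51, with 0 called over all genes or over the list alone (camera adjusted p = 1.75e-06, and 0.508 with an estimated correlation). Type I interferon response genes were higher, 23 of 26 with a positive fold change, 0 called over all genes and 1 adjusted over the list alone (Oasl2, 4.25 ± 1.06, an interferon-induced gene named after its value was seen; camera adjusted p = 0.00929, and 0.508 with an estimated correlation). Th17 genes were lower, 8 of 9 with a negative fold change. Of these, 1 was called over all genes (Rora, a nuclear receptor, -1.95 ± 0.30) and 2 adjusted over the list alone (Rora and Irf4, named after their values were seen; camera adjusted p = 0.0319, and 0.508 with an estimated correlation). The number of lists called, 4, was 2 without miR-24 replicate 1, 8 without miR-24 replicate 2 and 7 without control replicate 2 or 4. Ribosomal protein genes have many processed copies, so their counts are less certain. Dendritic and myeloid marker sums were higher in the miR-24 libraries, as given above, and the dendritic list shares Bst2 with the interferon list. The 16 measured miR-24 targets reported elsewhere did not pass (camera adjusted p = 0.667, 9 positive and 7 negative, median 0.03 although the camera statistic pointed lower, 0 called over all genes, and adjusted over the list alone the cell cycle inhibitors Cdkn2a higher and Cdkn1b lower, both named after their values were seen). The calcium and NFAT list had 2 members lower over all genes, and adjusted over the list alone Camk4 higher and Clcn3, Nfatc3 and Atp2b1 lower (Camk4 and Atp2b1 named after their values were seen; camera adjusted p = 0.0928).

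The comparison of miR-27a with control addressed the other microRNA of the series title. With miR-27a, 11 genes rose and 11 fell. Ikzf1, the lymphoid transcription factor Ikaros, fell from 1384 ± 128 to 674 ± 117 CPM (SD, n = 4 each; log2 fold change -1.04 ± 0.18), and its annotated 3-prime UTR holds the 8mer site ACTGTGAA of miR-27a at chromosome 11, 11772859 to 11772866 (GRCm38). Egr2, a transcription factor induced by T cell receptor signals, rose by 1.76 ± 0.31, to 64.3 ± 16.9 CPM. Angptl2, a secreted glycoprotein, rose by 2.99 ± 0.55, S100a4, a calcium-binding protein of motile and memory cells, by 2.21 ± 0.40, Iqgap3, a scaffold of proliferating cells, by 1.69 ± 0.25, and Sae1, a subunit of the SUMO-activating enzyme, by 1.20 ± 0.24.

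Genes of varied function fell with miR-27a. Nipal1, a magnesium transporter, changed by -2.85 ± 0.41, Tmsb10, an actin-binding peptide, by -2.20 ± 0.39, Cxadr, a junction adhesion molecule, by -2.04 ± 0.34, and Mrps33, a protein of the mitochondrial ribosome, by -2.03 ± 0.29. Dram2, a regulator of autophagy (-1.95 ± 0.36), Snap29, a membrane fusion protein (-1.86 ± 0.30), Alg11, an enzyme of N-glycan assembly (-1.56 ± 0.23), and Ccnk, a cyclin that acts in transcription (-1.30 ± 0.20), also fell. Of these 8 genes, all except Mrps33 hold an 8mer site of miR-27a, but Nipal1 and Ccnk were named by the rule for genes that hold one. Nipal1 had 0 reads in control replicate 1 and overlapped between the groups for that reason, and Tmsb10 has near-identical copies in the genome.

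For these 14 genes the edgeR adjusted p ranged from 0.00836 to 0.0471, among 1857 genes at an unadjusted p under 0.05 and 838 genes without overlap between the groups (chance gives 2.86%). With the replicate number as a block, which the check of same-numbered control and miR-27a libraries allowed, edgeR called 398 genes, 227 higher and 171 lower, and all 22 were among them. Alg11, Mrps33 and Nipal1 stayed under 0.05 without any 1 of the 8 libraries. The count was 7, 10, 5 and 79 without miR-27a replicate 1, 2, 3 and 4, and 6 and 10 without control replicate 3 and 4. Ikzf1, Dram2 and Tmsb10 were lost without miR-27a replicate 1, 2 or 3 or control replicate 3 or 4, Sae1 without these or control replicate 2, Snap29 without miR-27a replicate 1, 2 or 3 or control replicate 4, and Cxadr without miR-27a replicate 1, 2 or 3. Egr2 was lost without miR-27a replicate 1 or 3 or control replicate 2, 3 or 4, S100a4 without miR-27a replicate 1 or 3 or control replicate 2 or 4, Angptl2 without miR-27a replicate 2 or 3 or control replicate 2, 3 or 4, Ccnk without miR-27a replicate 3 or control replicate 3, and Iqgap3 without control replicate 3 (largest adjusted p 0.151, Sae1). DESeq2 called 154 genes.

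Targets of miR-27 reported elsewhere were lower with miR-27a. Of 18 measured, 16 had a negative fold change, 0 were called over all genes, and adjusted over the list alone 5 were lower (Il10, Fbxw7, Runx1, Ccng1 and Nfe2l2) and 1 higher (Rxra), of which all except Il10 were named after their values were seen. With the replicate block, 6 were lower and 1 higher over all genes, the same genes and Pparg, a nuclear receptor that was lower and was named after its value was seen. Fbxw7, a ubiquitin ligase subunit, stood at -1.15 ± 0.27 and Runx1, a transcription factor of T cell development, at -0.91 ± 0.25. Camera gave the list an adjusted p of 0.000915, and the adjusted p with an estimated correlation was 0.0252, the only list call among the 3 comparisons with control that held with it. Targets of miR-23 reported elsewhere were lower as well, with 14 of 17 fold changes negative and 0 called over all genes or over the list alone (adjusted p = 0.0174, and 0.442 with an estimated correlation).

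Genes of proliferation and of the respiratory chain were higher with miR-27a and the Th2 list was lower, in calls that did not hold with an estimated correlation. Camera adjusted p was 0.00249 for DNA replication and 0.0116 for the other 3 lists. The adjusted p with an estimated correlation was 0.627, 0.793, 0.646 and 0.646 for DNA replication, cell cycle, respiratory chain and Th2 genes. Of 31 DNA replication and G1/S genes, 26 had a positive fold change, 0 were called over all genes and 3 adjusted over the list alone (Mcm7, Rrm2 and E2f2, named after their values were seen). Of 30 cell cycle genes, 23 were positive, 0 called over all genes and 2 adjusted over the list alone (Ccnb1, a cyclin of mitosis, 1.13 ± 0.25, and Cdc20, both named after their values were seen). Of 26 nuclear genes of the mitochondrial respiratory chain, 21 were positive, with 0 called over all genes or over the list alone. Of 38 Th2 genes, 26 were negative, and Ikzf1 was called over all genes. Adjusted over the list alone, 2 were lower (Ikzf1 and Epas1, -1.48 ± 0.41) and 1 higher (Stat5b, 0.89 ± 0.24, a signal transducer of IL-2, named after its value was seen). With the replicate block, 6 Th2 genes were lower over all genes (Epas1, Ikzf1, Il10, Il2ra, Maf and Pparg) and 1 higher (Stat5b). It also called 1 gene each of the DNA replication, cell cycle and respiratory chain lists higher (Cdkn1a, Ccnb1 and Cox7a2). Of these, Il2ra, Pparg, Cdkn1a and Cox7a2 were named after their values were seen. With the block, camera called 10 lists in place of 6, adding Th17 genes (lower, adjusted p = 0.0386), naive and memory T cell genes (lower, 0.0220), cholesterol synthesis genes (higher, 0.0288) and ribosomal protein genes (higher, 0.0444). Without the block and with an estimated correlation, the camera adjusted p of these 4 lists was 0.646 for Th17 genes and 0.871 for the others. Without miR-27a replicate 1, 3 lists were called.

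The Th2 cytokine genes varied widely between libraries in this comparison. Il10, a cytokine that restrains inflammation, stood at 30.8 ± 34.7 CPM with miR-27a and 196 ± 115 CPM in the control group (SD, n = 4 each), a log2 fold change of -2.76 ± 0.91 with an edgeR adjusted p of 0.202. With the replicate block it was -2.88 ± 0.42 (edgeR adjusted p = 0.00262). Maf stood at -1.20 ± 0.47 (edgeR adjusted p = 0.267) and at -1.30 ± 0.30 with the block (0.0250). Il4 was at -0.74 ± 0.42, Il5 at 0.74 ± 0.68, Il13 at 1.44 ± 1.15 and Gata3 at -0.74 ± 0.40 (edgeR adjusted p from 0.413 to 0.633). Il4ra (0.19 ± 0.36), Stat6 (0.16 ± 0.25) and Nfatc2 (0.31 ± 0.26) did not pass the test in either fit. Of the list of anergy and E3 ligase genes, Egr2 rose and Ikzf1 fell over all genes and adjusted over the list alone (camera adjusted p of the list 0.772, with a median of -0.02 and a mean of 0.06).

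**Figure D1:**
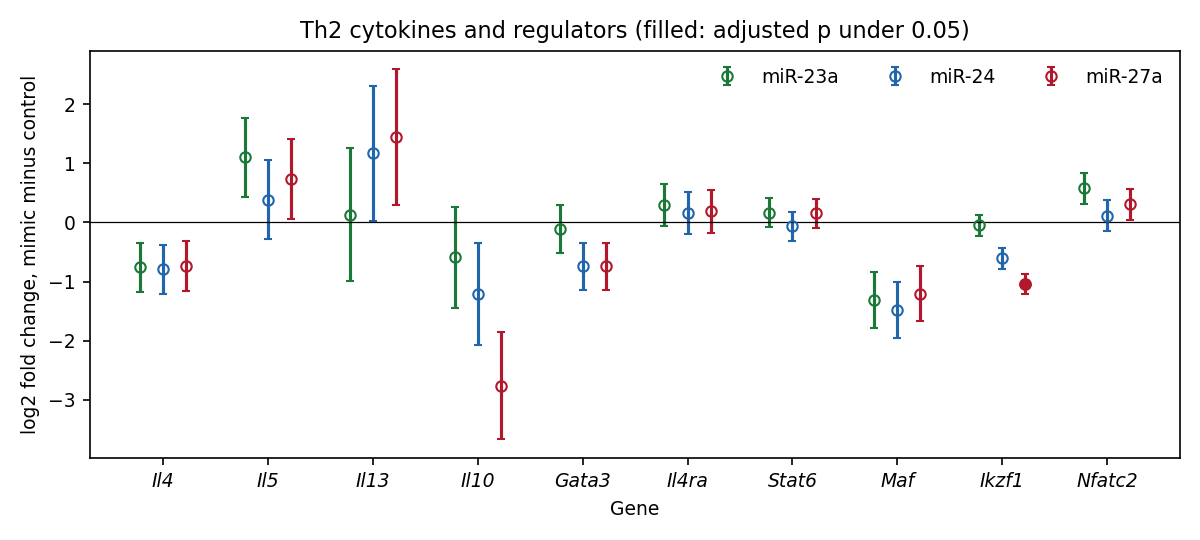
Log2 fold change (points) and its standard error (bars) of 10 Th2 genes with each mimic against the control mimic, n = 4 libraries per group, with filled points for an edgeR adjusted p under 0.05. Of the 30 values, all from the fit without the replicate block, only that of Ikzf1 with miR-27a, -1.04, passed. Il13 and Il10 have the widest bars. With the block, Il10 and Maf also passed with miR-27a. Maf and Ikzf1 passed with miR-24, whose libraries did not pass the pairing check with control.

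The set of transcripts with a seed site, a short match in the 3-prime UTR to bases near the start of the microRNA, was lower with each mimic that carries the matching seed. Of 12005 tested genes with an annotated 3-prime UTR, 3034 held a 7mer or 8mer site of miR-23a, 3241 of miR-24 and 3572 of miR-27a. With miR-23a, genes with its 8mer site had a median log2 fold change of -0.29, genes with its 7mer-m8 site -0.11, with its 7mer-A1 site -0.05, and genes without a site 0.15. With miR-27a these medians were -0.28, -0.06, -0.03 and 0.10, and with miR-24 -0.07, 0.05, -0.09 and 0.09. Against genes matched on 3-prime UTR length and expression, the difference between genes with and without a site shrank from -0.12 to -0.042 for miR-24, from -0.26 to -0.19 for miR-23a and from -0.19 to -0.13 for miR-27a. Sites of the mimic were found in 15 of the 17 genes lower with miR-23a, in 9 of the 11 lower with miR-27a and in 36 of the 72 lower with miR-24. Of these 72, 34 held a site of miR-27a and 26 of miR-23a (Fisher's exact p = 0.00177 and 0.0407). With miR-24 the median difference was -0.17 for miR-23a sites, -0.12 for miR-27a sites and -0.12 for its own. Of the 17, 2 held a site of miR-24 and 4 of miR-27a. Of the 11, 5 held a site of miR-23a and 4 of miR-24. Sh3bgrl, for example, holds the 8mer AATGTGAA of miR-23a at chromosome X, 109160313 to 109160320, and Sub1 the 8mer CTGAGCCA of miR-24 at chromosome 15, 11984207 to 11984214 (both GRCm38).

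The camera test of genes with against genes without a site gave p = 1.55e-08 for miR-23a, 0.000445 for miR-27a and 0.00805 for miR-24, and p = 0.000197, 0.000726 and 0.0170 with an estimated correlation. Adjusted over the 18 tests of 3 site sets in 6 comparisons, these were 2.80e-07, 0.00267 and 0.0207. For miR-24, leaving out control replicate 2 gave a median difference of -0.11 and an unadjusted p of 0.0703 in limma's camera. Fisher's exact test of sites among the genes that fell gave p = 8.48e-08, 0.000537 and 4.26e-05. Sites of the other mimics moved as well: genes with miR-23a sites were lower with miR-24 (camera adjusted p = 0.00922 over the 18 tests, limma) and with miR-27a (0.0245), and genes with miR-27a sites lower with miR-24 (0.0411). Sites of miR-24 did not pass with miR-23a (0.560) or miR-27a (0.804), nor did sites of miR-27a with miR-23a (0.0799). Per library, the median deviation of 8mer genes minus that of genes without a site was -0.25 ± 0.11 (SD, n = 4) in the miR-23a libraries for its own sites, -0.14 ± 0.05 for miR-24 and -0.24 ± 0.12 for miR-27a. The control libraries stood at 0.34 ± 0.30, 0.07 ± 0.08 and 0.28 ± 0.24 for the same sites (exact permutation p = 0.0286 each, two-sided, the smallest that 4 against 4 can give; 0.0643 adjusted over 9 tests). The same p was reached by a set that does not match, miR-27a sites in the miR-23a libraries (-0.0054 ± 0.070), and the other 5 such sets had exact p from 0.0857 to 0.686. Without control replicate 1, which stood at 0.73, 0.18 and 0.61, the control means were 0.21 ± 0.18, 0.034 ± 0.053 and 0.17 ± 0.10 (SD, n = 3; exact permutation p = 0.0286 each).

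**Figure D2:**
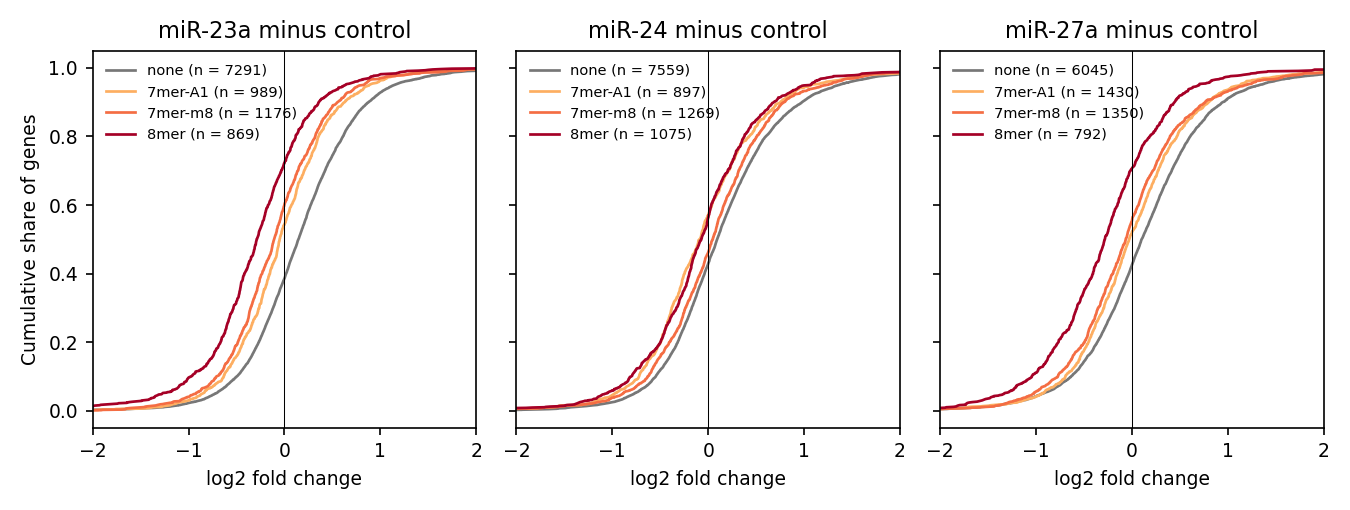
Cumulative share of genes (vertical axis) by log2 fold change against control (horizontal axis, drawn from -2 to 2) for genes without a site and with a 7mer-A1, 7mer-m8 or 8mer site of the transfected mimic, 1 panel per mimic. The 8mer curve lies to the left of the curve without a site, with medians of -0.29 against 0.15 for miR-23a, -0.07 against 0.09 for miR-24 and -0.28 against 0.10 for miR-27a.

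**Figure D3:**
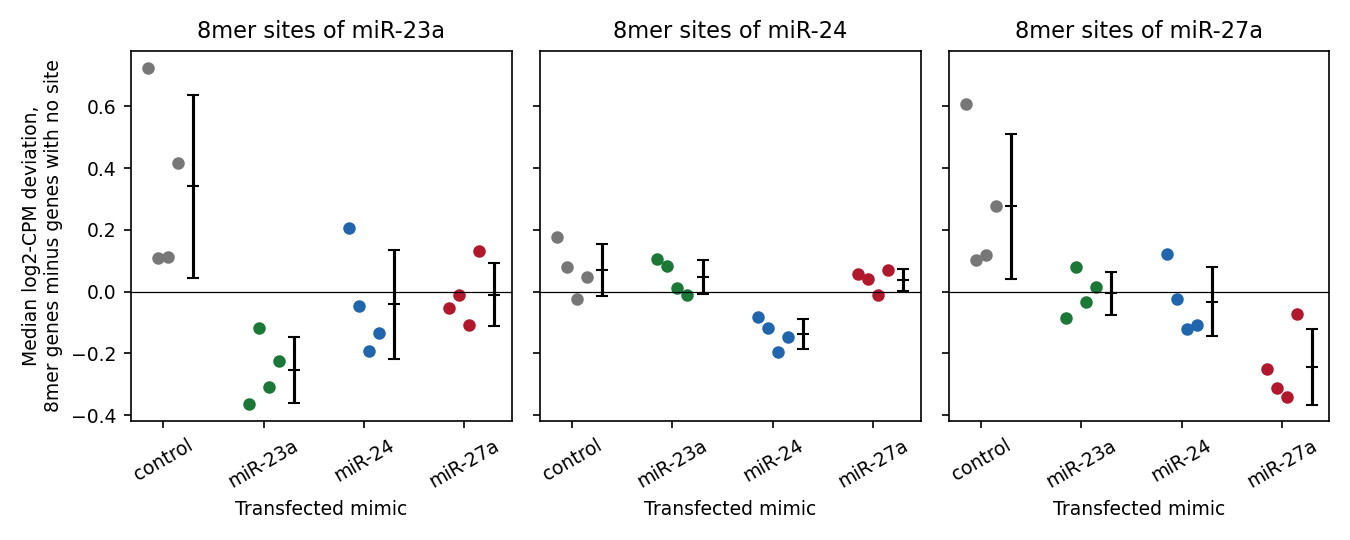
Median log2-CPM deviation of genes with an 8mer site minus that of genes without a site in each library (points), with the mean and SD of the 4 libraries of each group (bars), 1 panel per mimic's sites. The libraries that received the matching mimic averaged -0.25, -0.14 and -0.24 for miR-23a, miR-24 and miR-27a sites.

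The direct comparison of miR-24 with miR-27a asked where the effects of the mimics in the title differ. Plscr1, a membrane protein induced by interferon, was higher with miR-24, at 73.4 ± 17.6 CPM against 12.2 ± 3.42 CPM with miR-27a (SD, n = 4 each; log2 difference 2.57 ± 0.34). Psd3, a regulator of ARF proteins (2.38 ± 0.46), Epcam, an epithelial adhesion molecule (2.08 ± 0.45), Tmsb10 (1.88 ± 0.38), Cxadr (1.76 ± 0.32) and Pla2g4c, a phospholipase (1.74 ± 0.33), were higher too. Lower with miR-24 were Dgkk, a diacylglycerol kinase (-4.27 ± 0.95), Syt1, a calcium sensor of vesicle release (-2.27 ± 0.52), Uaca (-2.27 ± 0.34), Tcf7 (-2.22 ± 0.43), Bloc1s1, a factor of lysosome-related organelles (-2.20 ± 0.33), and Ttyh3 (-1.90 ± 0.45). Of the 10 fixed Th2 genes none was called: the log2 differences ran from -0.36 ± 0.61 for Il5 to 1.56 ± 0.87 for Il10, with Ikzf1 at 0.43 ± 0.17 (edgeR adjusted p = 0.278).

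In edgeR, 36 genes were higher and 78 lower with miR-24 than with miR-27a, among 1717 genes at an unadjusted p under 0.05 and 1217 without overlap (chance gives 2.86%), and the adjusted p of the 12 named genes ran from 0.00350 to 0.0495. The share of higher calls was 31.6%, and 48.2% with RLE size factors or 46.7% with upper-quartile factors, while DESeq2 called 260 genes, limma with sample weights 1012, a fit of the 8 libraries alone 21 and a fit of all genes without a filter 71. Bloc1s1, Plscr1 and Uaca kept their calls without any 1 of the 8 libraries. Dgkk, Syt1 and Ttyh3 lost theirs without any of the 8, with RLE or with upper-quartile factors (adjusted p from 0.0542 to 0.0590 under both), and Tmsb10 without any except miR-24 replicate 1. Without miR-24 replicate 2, 3 and 4 the count was 10, 14 and 62, and without miR-27a replicate 1, 2, 3 and 4 it was 41, 11, 36 and 72. Cxadr was lost without miR-24 replicate 2 or miR-27a replicate 1, 2 or 3, Psd3 without these or miR-24 replicate 3, Epcam without these or miR-24 replicate 3 or 4, Pla2g4c without miR-24 replicate 2 or 3 or miR-27a replicate 1, 2 or 4, and Tcf7 without miR-24 replicate 2, 3 or 4 or miR-27a replicate 1 or 2 (largest adjusted p 0.154, Dgkk).

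Genes of proliferation were lower with miR-24 than with miR-27a, and Th1 genes higher, in calls that did not hold with an estimated correlation. Of 30 cell cycle genes 27 were negative and of 31 DNA replication genes 27, with 0 called over all genes or over the list alone, and 19 of 26 respiratory chain genes were negative with 0 called in either way (camera adjusted p = 0.000153, 0.00243 and 0.0158, and 0.710 for each with an estimated correlation). Of 22 Th1 genes, 17 were positive, 2 were called over all genes and 3 adjusted over the list alone (Gzmb, a cytotoxic protease, 2.24 ± 0.50, Il18rap, 1.29 ± 0.29, and Il12rb2, 2.10 ± 0.57, both cytokine receptor chains, all named after their values were seen). Ribosomal protein genes were higher, with 30 of 40 positive, 0 called over all genes and 1 adjusted over the list alone (Rpl23, named after its value was seen), and interferon response genes higher, with 19 of 26 positive and 0 called in either way. Camera adjusted p was 0.0149 for Th1, 0.00628 for ribosomal and 0.0447 for interferon genes, and 0.710, 0.726 and 0.710 with an estimated correlation, with which no list was called (smallest adjusted p 0.510). Marker sums of other cell types went both ways: dendritic cell markers stood at 80.1 ± 17.0 CPM with miR-24 and 43.3 ± 6.15 CPM with miR-27a, and stromal and endothelial markers at 79.3 ± 9.34 and 138 ± 35.4 CPM, both without overlap. CD8 T, NK and gamma-delta T cell markers stood at 42.5 ± 12.2 and 25.7 ± 9.94 CPM and class II genes at 69.2 ± 31.5 and 125 ± 74.8 CPM (SD, n = 4 each). None of the 8 marker lists passed camera (smallest adjusted p = 0.401), but most of them had only 1 to 5 tested genes. Targets of miR-24 reported elsewhere had 12 of 16 negative differences, 0 called over all genes, and 1 higher and 5 lower adjusted over the list alone, and did not pass (camera adjusted p = 0.0619). Genes with miR-24 sites were lower with miR-24 than with miR-27a (an unadjusted p of 0.00256 in limma's camera, 52 of 78 lower genes). Genes with miR-27a sites did not pass in the other direction (an unadjusted p of 0.178 in limma's camera), although 21 of the 35 higher genes with an annotated 3-prime UTR held one (Fisher's exact p = 0.000259).

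The responses to miR-24 and miR-27a shared 6 called genes in edgeR. Genes higher with both included Noxo1, an organizer of an NADPH oxidase, Ptgr1, a reductase of prostaglandins, Iqgap3 and Sae1, and lower with both was Nipal1. Noxo1 and Ptgr1 have a mean log2-CPM of 0.23 and 1.98, below the minimum of 3 used elsewhere for named genes. Sae1 also lay above every control library with miR-23a (log2-CPM 6.47 to 7.47 against 5.70 to 6.35), while Iqgap3 and Nipal1 overlapped the controls there. Iqgap3 rose by 1.55 ± 0.25 with miR-24 and 1.69 ± 0.25 with miR-27a, and Nipal1 changed by -2.29 ± 0.39 and -2.85 ± 0.41. Independent lists of these sizes would share 0.0323 higher and 0.0611 lower genes, and 60 simulations of unchanged groups against the same controls shared a median of 0 in each direction and at most 1. The simulated groups held no changed genes, so a count near 0 was set in advance. Neither figure gives the number that lists of these sizes would share through common control libraries alone. With the 4 controls split between the comparisons, in 6 splits, the lists held 0 to 127 genes for miR-24 and 0 to 62 for miR-27a, too uneven for a count of shared genes. Across genes, which are not independent replicates, the fold changes had r = 0.610 against a simulated median of 0.558, and a covariance of 0.320 against 0.151 simulated, a difference of 0.170. With split controls the covariance ran from 0.0714 to 0.241. For miR-23a and miR-24, 2 genes were lower in both (Auh and Top1, a DNA topoisomerase), with a covariance of 0.266 against 0.150 simulated. Auh also lay below every control library with miR-27a (log2-CPM 5.05 to 6.20 against 6.27 to 6.65). For miR-23a and miR-27a no gene was shared in edgeR, with a covariance of 0.281 against 0.150 simulated.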

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

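The matched backgrounds were planned, but their bound as a test of an explanation, and the tests of comparisons without control libraries, of the replicate block and of the Th2 list without controls or without control replicate 1 were chosen only after the result was seen; the tests of 7-mer ranks, of other splits and of seed sites among Th2 genes were planned.

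Genes with seed sites of miR-23a, miR-24 and miR-27a were lower with the matching mimic. Long 3-prime UTRs or expression level as the whole cause are argued against by a matched background for miR-23a and miR-27a. There the difference shrank from -0.26 to -0.19 and from -0.19 to -0.13. For miR-24 it shrank from -0.12 to -0.042, so length or expression stays open as the cause of most of it. Without matching, genes with miR-23a and miR-27a sites also differed with miR-24, by -0.17 and -0.12. For each mimic a permutation test gave p = 0.0002, two-sided, the smallest that 10000 random lists can give. That test compares genes, which are not independent replicates, and does not measure the spread between libraries. Control libraries as the cause are argued against by comparisons between mimics, where the seed 7-mers of miR-23a, miR-24 and miR-27a ranked no lower than 1, 2 and 1 of 15735 toward lower with their mimic, although the camera test of all miR-27a sites against the mean of the other mimics gave an unadjusted p of 0.0535 (miR-23a 0.00213, miR-24 0.000141; limma). Against control the ranks were 1, 2 and 1. Of the 35 splits of each 8 libraries 1, the real one, had so small a camera p (1.55e-08, 0.00805 and 0.000445, best other 8.54e-08, 0.0123 and 0.000664). These shares hold only if the libraries of both groups are freely exchangeable, which is in doubt since many genes differed by replicate number. Among the 8 splits that part every same-numbered pair, the real one alone had so small a p, too few splits to reach the 0.05 level. The splits thus do not exclude chance. Binding of the mimics to these transcripts may explain the pattern; mimic dose in the cells was not measured, and secondary effects stay open.

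The replicate number as a block raised the calls with miR-27a from 22 to 398. Of 13824 assignments of numbers to libraries within groups, only the real one had so high a mean same-number correlation (share 7.23e-05), which argues against a chance match of numbers. With control replicate 1 left out, the block still called 11.1 times as many genes (321 against 29), which argues against that shallow library as the cause. The test had been worded for the miR-24 comparison, where the counts were 481 against 106, and was moved to miR-27a because, of the 3 comparisons with control, only that one passed the pairing check. A shared mouse, culture day or sequencing lane per number may explain it, and these cannot be told apart because the labels give none of them.

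The Th2 list was lower with miR-24 and with miR-27a in limma's camera, which did not hold with an estimated correlation (adjusted p 0.508 and 0.646). Whether the control libraries cause it is open: the mean of both mimics against miR-23a gave an unadjusted p of 8.70e-05 in limma's camera, but 0.0799 with an estimated correlation. Both values are from a fit without the replicate block, although miR-23a passed the pairing check with miR-24 and with miR-27a. The shallow control library as the cause is argued against by the camera p without it, which was 9.15e-07 for miR-24 and 0.000515 for miR-27a with the list still lower, each smaller than with it; this bound was settled after these values were seen, and an estimated correlation, with 0.0401 and 0.129 without that library and 0.0430 and 0.147 with it, cannot decide for miR-27a. Whether members with a seed site fell more is open: the medians were -0.61 for 22 values with a site and -0.43 for 54 without (one-sided permutation p = 0.240), and by mimic -0.52 against -0.55 for miR-24 and -0.74 against -0.29 for miR-27a. Each of the 38 genes enters these values once per mimic, and both mimics share the control libraries, so the values are not independent. Chance cannot be excluded, since 3 of 35 splits for miR-24 (real 2.99e-06, lowest other 3.03e-09) and 5 of 35 for miR-27a (0.00144 and 4.40e-06) gave a camera p as small; 21 of the 38 genes differed by replicate number, which cancels in the real groups but not in most splits, and of the 8 splits that part every same-numbered pair 1 for miR-24 and 2 for miR-27a gave a p as small, too few splits to reach the 0.05 level.

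For the counts of called genes, 1 of 35 splits gave as many as the 17 of miR-23a (highest other 0) and 1 as many as the 114 of miR-24 against miR-27a (highest other 1). These shares lie under the 0.05 level only if the libraries of both groups are freely exchangeable. Many genes differed by replicate number, so this is in doubt, and chance is not excluded. For miR-24 it was 2 of 35 (110 genes, and 139 for miR-24 replicate 1 with controls 1, 3 and 4) and for miR-27a 2 of 35 (22 genes, and 50 for miR-27a replicates 1, 2 and 3 with control replicate 2), so chance cannot be excluded at that level, and the larger counts point to a structure of the libraries. The splits with 139 and 50 genes do not part every same-numbered pair. Among the 8 splits of each comparison that do, the real one alone gave as many genes. The highest other count was 0 for miR-23a, 1 for miR-24, 0 for miR-27a and 0 for miR-24 against miR-27a. Of these comparisons only miR-27a against control passed the pairing check, and 8 splits are too few to reach the 0.05 level. For the gene lists, 28, 25 and 12 of 35 splits gave as many as the 2, 4 and 6 lists of miR-23a, miR-24 and miR-27a (highest other 8, 11 and 11), and chance cannot be excluded.

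In 26 of 280 groups of 4 libraries, from 8 library measures and 62 named genes, 1 library stood far from the other 3; chance flags about 1 in 20 groups. Of the 26, 8 were control replicate 1, with 7292 genes with a read (others of its group 14175 to 14744) and a log2-CPM of -2.05, which is 0 reads, for Abcb1b, Amica1, Bloc1s1, Hbegf, Nipal1, Pla2g4c and Tada2b. Gene reads were 4086654 in miR-23a replicate 2 (others 11370150 to 12582408). Dgcr8 stood at 41.8 CPM, a log2-CPM of 5.39, in miR-24 replicate 1. In the same library the log2-CPM was 5.67 for Avl9, 2.86 for Il10 (others 6.56 to 7.25) and 3.93 for Sft2d1. It was 4.25 for Abcb1b and 4.64 for Klf2 in miR-23a replicate 4, 6.25 for Maf in miR-23a replicate 1 (others 7.50 to 7.55) and 1.46 for Syt1 in miR-23a replicate 2. It was 0.71 for Syt1 and 1.95 for Uaca in miR-24 replicate 2, and 1.22 for P2rx7, 6.60 for Rps29 and 5.32 for Slc7a5 in miR-24 replicate 4. It was 3.4 for Cxadr and 6.17 for Rps29 in miR-27a replicate 4, and 6.44 for Hmgn2 in control replicate 4 (others 7.61 to 7.73).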

How the results depend on the processing

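The block without control replicate 1 and the library sizes without Rn45s were chosen only after the data were seen; all other settings were planned. Outside the fits without 1 library, 844 values of named genes kept their direction and side of the threshold, 43 lost the threshold, 12 gained it and 31 changed sign.

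Counts of called genes moved more than 1.5 times under these settings, in the order miR-23a, miR-24 and miR-27a against control and miR-24 against miR-27a where all are given. The replicate block called 55, 591, 398 and 572, and the block without control replicate 1 called 35, 481, 321 and 549. DESeq2 called 44, 225, 154 and 260. The libraries of both groups alone gave 2 for miR-23a, 34 for miR-24 and 21 for miR-24 against miR-27a, with fewer libraries to estimate the spread. No filter gave 71 for miR-24 against miR-27a, with more genes tested, and limma with sample weights 1012. The causes of these changes were not tested. RLE and upper-quartile factors, the filter of 1 CPM and library sizes without Rn45s kept these counts within 1.5 times. Without 1 library the counts ran from 8 to 19, 35 to 158, 5 to 79 and 10 to 104.

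Gene lists called numbered 0, 0 and 1 for miR-23a, miR-24 and miR-27a with an estimated correlation and 4, 9 and 10 with the block; without 1 library they ran from 1 to 4, 2 to 8 and 3 to 9. The genes shared by miR-24 and miR-27a numbered 115 with the block (the cause was not tested) and a median of 0 with split controls, where some of the smaller groups called no gene at all. The site differences kept their sign and threshold, but not their size, under 8mer sites only, sites in any 3-prime UTR, an estimated correlation, the block and the matched background, and without 1 library except miR-24 without control replicate 2 (-0.14 to -0.11, p up to 0.0703). The difference of miR-24 fell from -0.12 to -0.042 with the matched background, and that of miR-27a grew from -0.19 to -0.34 with 8mer sites only.

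In the comparisons whose groups did not pass the pairing check, the block called Maf (edgeR adjusted p = 0.0209) and Ikzf1 (0.0425) lower with miR-24. The block also called Il10 (0.0219) higher with miR-24 than with miR-27a. For miR-27a against control it changed, among the genes named by the rule for that comparison, the calls of Il10 and Maf alone, and the calls of list members given with the results.

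Outside the fits without 1 library, signs changed only among Th2 genes, whose reversed values were not called (smallest adjusted p 0.209, limma), and the cause was not tested. For miR-24 against miR-27a, log2 values turned positive for Il4 (0.011 with RLE, 0.021 with upper-quartile factors, 0.0029 with the block, 0.0034 with the block without control replicate 1, 0.012 with DESeq2, 0.29 with limma), Gata3 (0.063, 0.065, 0.040, 0.039, 0.065 and 0.69 in that order, and 0.021 without a filter, 0.00086 with the filter of 1 CPM, 0.021 in the libraries of both groups and 0.0058 without Rn45s), and Il4ra (0.031 with RLE, 0.043 with upper-quartile factors, 0.031 with DESeq2, 0.30 with limma). With limma, Il13 was 1.93 and Maf 0.53 there, and Il13 -0.64 and Il4ra -0.0036 for miR-27a against control. Stat6 with miR-24 was 0.018 with RLE, 0.026 with the block, 0.034 with the block without control replicate 1 and 0.012 with DESeq2, Il5 with miR-24 -0.090 with the block, and Gata3 with miR-23a 0.015 and 0.026 with these blocks.

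Without 1 library the sign changed for miR-23a in Gata3 (-0.37 to 0.23), Ikzf1 (-0.088 to 0.030), Il13 (-0.48 to 0.41) and Stat6 (-0.053 to 0.41), for miR-24 in Il4ra (-0.17 to 0.39), Il5 (-0.11 to 0.87), Nfatc2 (-0.026 to 0.37) and Stat6 (-0.26 to 0.20), and for miR-27a in Il4ra (-0.042 to 0.40) and Stat6 (-0.059 to 0.41). For miR-24 against miR-27a it changed in Gata3 (-0.29 to 0.26), Il13 (-1.41 to 1.13), Il4 (-0.35 to 0.23), Il4ra (-0.35 to 0.20), Il5 (-0.83 to 0.031) and Maf (-0.56 to 0.49). Depth limits control replicate 1, where 1 read is 16.3 CPM. In data simulated and tested with the spread of the fit without a block, 2-fold changes were recovered in 17.9% to 22.4% of changed genes. These were drawn from genes with a mean log2-CPM of at least 3. Changes of that size are thus mostly missed by that fit. Recovery with the block was not simulated.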

Other observations

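The tests of the replicate block were chosen only after the result was seen, and those of the control mimic were planned. Many genes differed by replicate number across all 4 groups. In an edgeR fit with the number as a block, 1768 of 12952 genes (13.7%) had an adjusted p under 0.05 for it. They included 17 of 24 T cell activation and immediate early genes, 11 of 17 Treg genes, 21 of 38 Th2 genes and 12 of 22 Th1 genes, but 4 of 40 ribosomal protein genes and 2 of 26 respiratory chain genes. Among the Th2 genes were Pparg (adjusted p = 5.06e-06), Il9 (1.63e-05), Il10 (0.000381), Gata3 (0.000489), Il13 (0.00149) and Il4 (0.00610).

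Among all 7-mers, the seed match AATGTGA ranked 1 with miR-23a (t = -12.2), ACTGTGA 1 with miR-27a (t = -9.71) and CTGAGCC 2 with miR-24 (t = -7.06), where TGAGCCA, the 7mer-A1 match of the same seed, ranked 1 (t = -8.48).

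The control mimic may itself carry a seed that lowers transcripts in the control libraries. For cel-miR-67, a worm microRNA often used as a control mimic, the match GGTTGTG ranked 2, 164 and 20 among the most positive 7-mers with miR-23a, miR-24 and miR-27a, so whether the control mimic carries that seed is open. The match of cel-miR-239b ranked 1529 at best, which argues against it. The sequences of both are from general knowledge.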
